A study of Mus musculus with 6 samples.

How the data were processed

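RNA of cardiomyocytes isolated by retrograde perfusion from H19 knockout mice and wild-type littermates, 6 weeks after TAC, was labelled and hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. The 6 arrays, 3 per genotype, were grouped by the genotype in their labels. Per the file headers, the scanner output was made with Agilent Feature Extraction 10.7.3.1, which gives for each spot a background-subtracted and detrended intensity that is not normalized between arrays, the mean and local background intensity, and flags for spots well above background, saturated or non-uniform. Probe coordinates follow the mm9 build, per the file headers. The authors' deposited value table holds an intensity per spot on a linear scale, not centred. Its columns have a rank correlation of 1 with the scanner's processed intensity of the same array and the same median of 69.7 in all 6, so it was quantile-normalized; the tool is not given in the sources used here. The labels name gene set enrichment analysis, without its mode or sets.

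The log2 of the processed intensity was taken and the array's 75th percentile subtracted. These percentiles ranged from 774 to 1152. The 3671 control spots of an array and spots marked as outliers were left out, spots of a probe were averaged, and 32 of 55681 probes without a usable spot on every array were left out. Probes well above background on at least 3 of the 6 arrays were kept (29990), and each gene was represented by its probe with the highest mean over all arrays, giving 21888 genes, 13906 of them with symbols that are not predicted or clone names. Of 5708 genes with more than 1 tested probe, 2 were called, and 1 of these (Klhl31) had a probe of opposite sign. Names were updated through a RefSeq table of assembly GRCm38.p6 used for names only: 26425 probes matched by accession, 3988 by symbol and 826 by synonym, and 24442 kept the name in the file. No column of another sample was used. The value of 1 member of an added list is not reported here.

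Genotypes were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), as knockout minus wild type, with Benjamini-Hochberg adjustment at 0.05 over all genes; all adjusted p-values of genes are from this test. Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 43 lists; 73 of 824 list genes were not tested because they were dim or had no probe. Camera was also run with the correlation estimated for each list, beside the rotation test fry and preranked GSEA (fgsea 1.28.0, 10000 permutations). An exact permutation test of 3 against 3 arrays cannot give a p under 0.10. Where a probe was not well above background in one genotype, the bound on the fold sets the brighter mean against, per array of the dimmer genotype, the higher of the lowest signal well above background and the probe's own.

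The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes H19, the genes past the threshold with non-overlapping arrays, the next genes by p up to 10 per direction, up to 4 members of each list by smallest p and a fixed panel of cardiac genes; from the list members the text names a part, mostly of lists that were shifted. Alternatives were normexp background correction with offset 50, quantile normalization, scaling to the median of all probes, the authors' deposited values, other filters on dim probes, the mean of a gene's probes, replicate number or slide as a block, an intensity trend with a robust prior, array weights, other thresholds, other list tests, and leaving out each array in turn. Leaving out genes of chromosome 9 was added after the data were seen. With 1 array left out, a genotype keeps 2 arrays and the spread is pooled over both genotypes.

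The procedure was tested on simulated data with 21888 genes, 50 of them changed at each fold. It recovered 0 of 50 genes at 1.5-fold, 14 of 50 at 2-fold, 50 of 50 at 4-fold and 48 of 50 at 8-fold, with 5 false calls, and for the lists it found the shifted list and called 0 others. The simulated genes varied independently of each other. The simulation therefore does not show how often lists whose genes vary together are called falsely. Its shifted list was moved 2-fold in all members, more than the fibroblast median of 0.60 (log2) in the real data. Its spread was drawn from the variances of the fit, and its planted changes outnumbered the 8 genes that passed in the real data. More changed genes ease the adjustment, so the recovered counts may be higher than these arrays would give. In the real data Plaat1, at 9.55-fold, did not pass. The signal over background, between 48.8% and 58.6% of spots on an array, and the number of arrays limit what can be detected.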

Results

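H19 is an imprinted long non-coding RNA, and the arrays address which cardiomyocyte transcripts differ in its absence when the heart works against a raised pressure. Transverse aortic constriction (TAC) is an operation that narrows the aortic arch and loads the left ventricle. Cardiomyocyte fractions were profiled 6 weeks after TAC on 1-colour Agilent mouse arrays, 3 from H19 knockout mice and 3 from wild-type littermates. Unoperated hearts were not analysed here, so every difference below is one between genotypes under load. Between 48.8% and 58.6% of the 59305 non-control spots of an array were well above background, and no spot was saturated. Pearson correlations between arrays, over genes, ranged from 0.981 to 0.990 within the genotypes and from 0.981 to 0.990 between them. Replicate 1 of each genotype lay on slide 1, and replicates 2 and 3 of each lay on slide 2. The labels call the mice littermates and do not say that each array held RNA of 1 mouse, so the p-values measure the spread between these samples. The number of arrays limits the precision of each value.

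H19 itself was not well above background on any of the 3 knockout arrays and was readily detected in wild type. Its brightest probe, on chromosome 7 from 149761492 to 149761551 (mm9), read 1.09 ± 0.52 in wild type and -6.01 ± 0.37 in knockout (log2 signal relative to the array's 75th percentile, SD, n = 3 each). The level was at least 32.4-fold higher in wild type, a bound that sets the wild-type mean against the detection floor of the knockout arrays, and the fitted log2 difference was -7.11 (SE 0.31, adjusted p = 0.00185). Of the 7 H19 probes, 5 were well above background on all 3 wild-type arrays, 1 on 2 arrays and 1 on none, and none was so on a knockout array. The part of the gene that the knockout allele lacks is not given in the sources used here. The difference was -7.36 on slide 1 (1 array against 1) and -6.98 on slide 2 (2 against 2). Igf2, the paternally expressed neighbour of H19, has 1 probe, which was not well above background on any array (0 of 6), so it was not tested.

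Beside H19, 5 genes with established symbols differed between the genotypes. Manba, which encodes lysosomal beta-mannosidase, and Tmem100, a membrane protein of the endothelial BMP pathway, rose in the knockout. Snap91, a clathrin adaptor, Angptl4, a secreted inhibitor of lipoprotein lipase, and Klhl31, a kelch protein of striated muscle, fell. Manba rose from 0.95 ± 0.19 to 3.05 ± 0.19 (log2 difference 2.10, SE 0.18, 4.27-fold) and Tmem100 from -1.44 ± 0.39 to 0.92 ± 0.14 (2.36, SE 0.22, 5.12-fold). Snap91 went from 0.03 ± 0.46 to -2.72 ± 0.07 (log2 difference -2.75, SE 0.24, 6.74-fold lower). Angptl4 went from 1.95 ± 0.19 to -0.05 ± 0.20 (-1.99, SE 0.18, 3.98-fold lower), and Klhl31 from 3.98 ± 0.36 to 1.62 ± 0.19 (-2.36, SE 0.22, 5.15-fold lower). Each of these 5 had an adjusted p of 0.0433 (limma, n = 3 each). The probes lie at chromosome 3, 135234096 to 135234155 for Manba, chromosome 11, 89897263 to 89897322 for Tmem100, and chromosome 17, 33911880 to 33911939 for Angptl4 (mm9). Those of Snap91 (86660081 to 86660140) and Klhl31 (77503483 to 77503542) both lie on chromosome 9, as do the 2 further genes that passed, which carry clone names and both fell. A second Klhl31 probe, at 77506749 to 77506808, gave 0.15 (SE 0.23), and the mean of the Klhl31 probes gave -1.10 with an adjusted p of 0.442.

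In all, 8 of 21888 genes passed an adjusted p of 0.05, 2 higher and 6 lower in knockout, and 233 were higher and 1501 lower at an unadjusted p under 0.05, where chance gives 1094.4. This balance depended on the scaling: it was 489 higher and 783 lower with quantile normalization, and 1561 and 241 with scaling to the median of all probes. The 3 arrays of one genotype lay beyond the other 3 for 10.5% of genes, where chance gives 10%. Other splits of the 6 arrays into 3 and 3 gave from 161 to 3517 genes at an unadjusted p under 0.05, and the split by genotype gave 1734. With slide as a block H19 alone passed (adjusted p = 0.000368), and the 5 named genes had adjusted p from 0.0929 to 0.123. Leaving out wild-type replicate 1 left 4 genes and wild-type replicate 3 left 3, of which only H19 was among the 8, while leaving out any one of knockout replicates 1, 2 or 3 or wild-type replicate 2 left 1, H19.

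**Figure D1:**
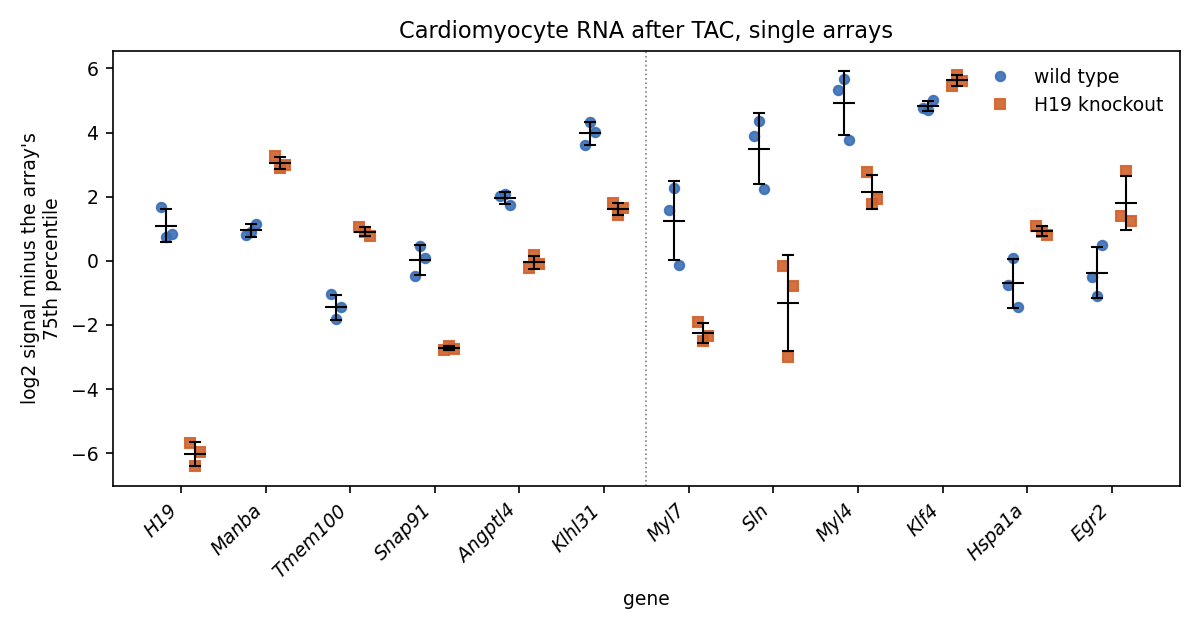
The vertical axis is log2 signal minus the array's 75th percentile, for each array (points) with the group mean and SD (bars, n = 3), in wild type and H19 knockout; genes left of the dotted line passed an adjusted p of 0.05 and those to its right did not. H19 read 1.09 in wild type and -6.01 in knockout, and Manba 0.95 and 3.05.

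The next genes by p, which did not pass the correction, are given as values. Higher on all 3 knockout arrays than on any wild-type array were Plaat1, a phospholipase and acyltransferase (log2 difference 3.26, SE 0.41, adjusted p = 0.199), Pdxdc1 (1.27, SE 0.16), Pxylp1 (1.29, SE 0.20), Abhd14b (1.78, SE 0.29) and Uchl1, a ubiquitin hydrolase (1.42, SE 0.25). Dlk1 (1.97, SE 0.35, well above background on 1 wild-type array), Trim16 (1.37) and Plcxd1 (1.31, well above background on 2 wild-type arrays) followed. Lower on all 3 were Elobl (-1.13, SE 0.17), Atp10d, a phospholipid flippase (-1.52, SE 0.23), Pigx (-1.03), Fam169a (-1.09, well above background on 1 knockout array), Myl7 (-3.50, SE 0.57) and Sln (-4.82, SE 0.83). Their adjusted p-values ran from 0.199 to 0.578. Pxylp1, Abhd14b and Sln are also on chromosome 9.

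No marker of hypertrophy passed the test over all genes. The natriuretic peptide genes Nppa and Nppb had log2 differences of 0.04 (SE 0.15) and 0.18 (SE 0.18), the myosin heavy chains Myh6 and Myh7 -0.21 (SE 0.14) and 0.19 (SE 0.40), skeletal actin Acta1 0.03 (SE 0.27) and Ankrd1 -0.06 (SE 0.15). No member of the hypertrophy and fetal list passed, over all genes or adjusted over the list alone. As a list it lay higher than other genes, with 8 of 10 members higher and a median of 0.09 (camera adjusted p = 0.0272), a call lost with an estimated correlation (adjusted p = 0.831 with an estimated correlation). Ccn2 (0.47, SE 0.20) and Gdf15 (1.07, SE 0.57) were its members with the smallest p. The median was 0.53 on slide 1 and -0.11 on slide 2, and without wild-type replicate 1 it was -0.07 (adjusted p = 0.905) and without knockout replicate 2 it was 0.09 (adjusted p = 0.183). Without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3 it was 0.16, 0.23 and 0.16, with the call kept.

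Most of the calcium and calcineurin genes named here showed small values, and Sln a large one (-4.82, SE 0.83). Tesc, which encodes a calcineurin-binding EF-hand protein, differed by -0.01 (SE 0.19), and Rcan1, a calcineurin target gene, by 0.49 (SE 0.40), both with no call. Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.04 (SE 0.16), its regulator Pln by 0.08 (SE 0.18) and the release channel Ryr2 by -0.03 (SE 0.19). The calcineurin and NFAT list had 16 of 25 members higher and a median of 0.03 (adjusted p = 0.0347, and adjusted p = 0.627 with an estimated correlation). Its median was 0.31 on slide 1 and -0.07 on slide 2. The call was lost without wild-type replicate 1 (0.01, adjusted p = 0.285), knockout replicate 1 (-0.04, adjusted p = 0.136) or knockout replicate 2 (0.07, adjusted p = 0.0545), and the median was 0.08, 0.09 and 0.07 without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3. The calcium handling list was not shifted (median 0.08, mean -0.18, adjusted p = 0.0857), and its 1 member past the threshold adjusted over the list alone was Sln, against 0 over all genes.

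Immediate early and heat shock genes, which respond within minutes to many stimuli, were higher in the knockout as a list: 25 of 25 measured members had a positive difference, with a median of 0.48 (adjusted p = 2.92e-18, and adjusted p = 0.527 with an estimated correlation). None passed over all genes, and 4 rose when adjusted over the list alone: Klf4 (0.80, SE 0.16), the heat shock gene Hspa1a (1.62, SE 0.37), Egr2 (2.17, SE 0.53) and Fosb (1.13, SE 0.30). The median was 1.08 on slide 1 and 0.35 on slide 2. Without wild-type replicate 3 the median was 0.76.

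The list of unfolded protein and integrated stress response genes had 21 of 23 members higher and a median of 0.16 (adjusted p = 5.23e-06, and adjusted p = 0.627 with an estimated correlation). Atf4, the transcription factor of the response, differed by 0.32 (SE 0.15) and its target Ddit3 by 0.60 (SE 0.20). No member passed, over all genes or adjusted over the list alone. The median was 0.36 on slide 1 and 0.02 on slide 2; without wild-type replicate 1 it was 0.05, without wild-type replicate 2 0.27 and without wild-type replicate 3 0.29. Genes of the p53 list were higher in 12 of 17 cases, with a median of 0.08 (adjusted p = 0.0207, and adjusted p = 0.527 with an estimated correlation), among them Bax (0.71, SE 0.21) and Cdkn1a (0.69, SE 0.30). The p53 call was lost without wild-type replicate 3 (0.13, adjusted p = 0.0888) and without knockout replicate 3 (0.06, adjusted p = 0.0518), and the median was 0.12 without wild-type replicate 2. The hypoxia list had 10 of 14 members higher and a median of 0.06 (adjusted p = 0.0347, and adjusted p = 0.627 with an estimated correlation), with Adm at 0.69 (SE 0.21). It was 0.32 on slide 1 and -0.01 on slide 2, and the call was lost without wild-type replicate 1 (0.04, adjusted p = 0.157), knockout replicate 1 (0.03, adjusted p = 0.121) or wild-type replicate 3 (0.07, adjusted p = 0.0524), with 0.10 without wild-type replicate 2.

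Genes of fibroblasts and of the extracellular matrix were higher in the knockout as lists, and 1 knockout array stood above the rest. All 15 fibroblast markers had a positive difference, with a median of 0.60 (adjusted p = 1.01e-07, and adjusted p = 0.627 with an estimated correlation), for instance the proteoglycan gene Dcn (0.65, SE 0.26) and Dpt (0.95, SE 0.39). Of the matrix genes 21 of 24 were higher, with a median of 0.54 (adjusted p = 1.01e-07, and adjusted p = 0.627 with an estimated correlation), with Thbs1 at 1.68 (SE 0.53), Mmp2 at 1.22 (SE 0.54), Col1a1 at 0.57 (SE 0.57), Col3a1 at 0.43 (SE 0.52) and Postn at 0.27 (SE 0.67). No member of these lists passed, over all genes or adjusted over the list alone. Relative to each gene's mean over the 6 arrays, fibroblast markers averaged 1.19 in knockout replicate 2, against -0.32 and 0.11 in the other knockout arrays and 0.27, -0.37 and -0.88 in wild type. Without knockout replicate 2 the fibroblast median was 0.17 (adjusted p = 0.0171) and the matrix median 0.03 (adjusted p = 0.141), and without wild-type replicate 3 they were 0.34 and 0.29; the matrix median was 0.95 without knockout replicate 1. On slide 1 the medians were -0.63 and -0.83, and on slide 2 they were 1.10 and 1.23.

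Markers of other cell types moved in different directions. Macrophage and myeloid markers were lower in 22 of 22 cases, with a median of -0.50 (adjusted p = 0.00324, and adjusted p = 0.831 with an estimated correlation), among them Lyz2 (-0.58, SE 0.29) and Ctss (-0.76, SE 0.39). The macrophage call was lost without knockout replicate 1 (-0.30, adjusted p = 0.414), wild-type replicate 3 (-0.37, adjusted p = 0.555) or knockout replicate 3 (-0.36, adjusted p = 0.0518) and reached -0.85 without knockout replicate 2, and the median was -0.65 on slide 1 and -0.47 on slide 2. For mesothelial markers the median was 0.40 in 6 genes (adjusted p = 0.0256, and adjusted p = 0.627 with an estimated correlation), with Msln at 0.82 (SE 0.39). That call was lost without wild-type replicate 2 (0.26, adjusted p = 0.0647), knockout replicate 2 (0.04, adjusted p = 0.512) or wild-type replicate 3 (0.34, adjusted p = 0.144), and the median was 0.82 without knockout replicate 1. For lymphocyte markers it was 0.31 in 9 genes (adjusted p = 0.0393, and adjusted p = 0.831 with an estimated correlation), with Lck at 2.70 (SE 0.88), well above background on 1 wild-type array and on 3 knockout arrays, and at -0.15 on slide 1 and 4.12 on slide 2. Their call was lost without wild-type replicate 2 (0.32, adjusted p = 0.0545), knockout replicate 2 (0.34, adjusted p = 0.272), wild-type replicate 3 (0.03, adjusted p = 0.555) or knockout replicate 3 (-0.01, adjusted p = 0.316), with medians of 0.86 without wild-type replicate 1 and 1.01 without knockout replicate 1. On slides 1 and 2 the medians were -0.42 and 0.86 for mesothelial and -0.83 and 1.35 for lymphocyte markers.

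**Figure D2:**
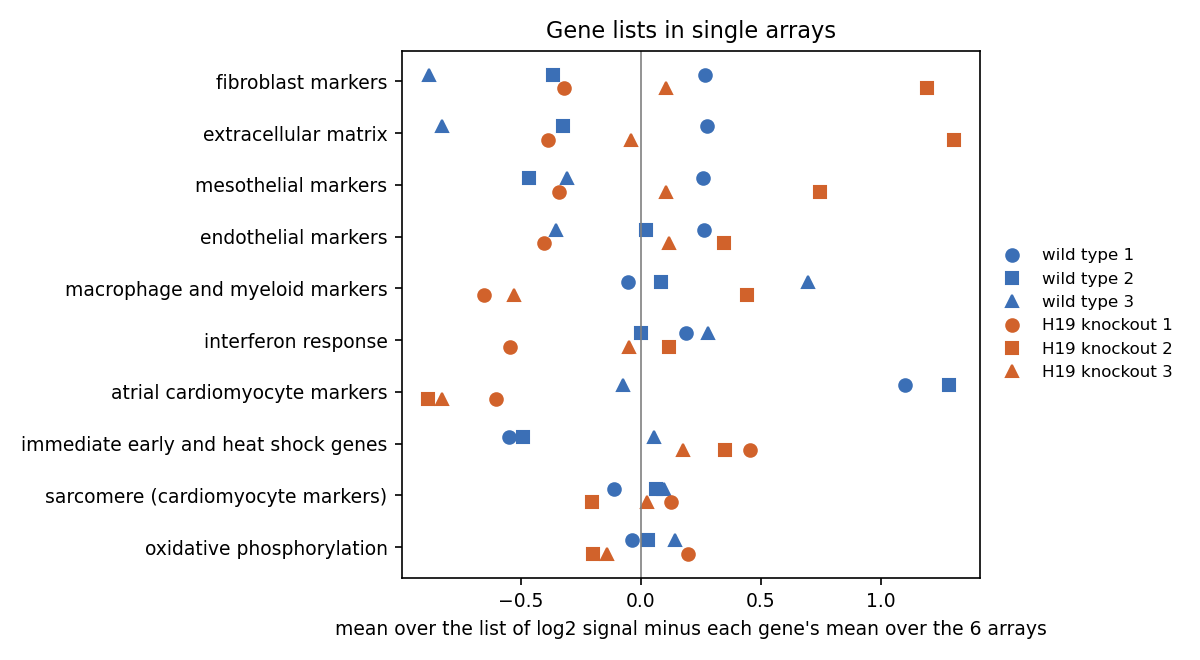
The horizontal axis is the mean over a list's genes of log2 signal minus each gene's mean over the 6 arrays, and each symbol is 1 array of wild type or H19 knockout. Fibroblast markers averaged 1.19 in knockout replicate 2, and atrial markers lay at -0.60, -0.88 and -0.83 in knockout.

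Interferon response genes were lower in 22 of 25 cases, with a median of -0.29 (adjusted p = 0.0207, and adjusted p = 0.831 with an estimated correlation), a median that was 0.13 with scaling to the median of all probes, which moved the median of all genes from -0.05 to 0.37. Gbp3, an interferon-induced GTPase, differed by -1.18 (SE 0.33) and Ifi44 by -0.40 (SE 0.17), neither past the threshold over all genes or adjusted over the list alone. The interferon call was lost without knockout replicate 1 (-0.15, adjusted p = 0.987) or wild-type replicate 3 (-0.27, adjusted p = 0.193), and the median was -0.46 without knockout replicate 2. The macrophage markers were lower in the same comparison (-0.50). The median was -0.73 on slide 1 and -0.22 on slide 2.

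The list of atrial cardiomyocyte markers was lower in the knockout, with 3 genes far below the rest. Myl7 and Myl4, the atrial myosin light chains, and Sln, the atrial regulator of the calcium pump, had log2 differences of -3.50 (SE 0.57), -2.78 (SE 0.52) and -4.82 (SE 0.83). These 3 fell when adjusted over the list alone, and 0 did over all genes, where their adjusted p-values were 0.462, 0.578 and 0.513. The list's median was -0.10 and its mean -1.54, with 5 of 7 members lower (adjusted p = 0.0356, and adjusted p = 0.627 with an estimated correlation), and the median was 0.32 with scaling to the median of all probes. Nr2f1, an atrial transcription factor, differed by 0.44 (SE 0.29). On slide 1 the differences of Myl7, Myl4 and Sln were -3.52, -2.58 and -4.06, and on slide 2 they were -3.49, -2.88 and -5.20. The call was lost without wild-type replicate 1 (-0.12, adjusted p = 0.0916), knockout replicate 1 (-0.27, adjusted p = 0.11), wild-type replicate 2 (-0.15, adjusted p = 0.0647) or knockout replicate 3 (-0.11, adjusted p = 0.0518), and the median was -0.70 without knockout replicate 2 and -0.60 without wild-type replicate 3. It was also lost without genes of chromosome 9, among them Sln (-0.08, adjusted p = 0.222), a choice made after the data were seen.

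Signalling lists were higher by small amounts. The list of TGF-beta signalling and targets had 12 of 15 members higher with a median of 0.10 (adjusted p = 0.0256, and adjusted p = 0.627 with an estimated correlation); the call was lost without knockout replicate 2 (0.04, adjusted p = 0.989) or wild-type replicate 3 (0.13, adjusted p = 0.0772), the median was 0.22, 0.17 and 0.22 without knockout replicate 1, wild-type replicate 2 or knockout replicate 3, and fibroblast markers were highest in knockout replicate 2 (1.19). The list of insulin and IGF signalling had 14 of 20 members higher with a median of 0.16 (adjusted p = 0.0256, and adjusted p = 0.527 with an estimated correlation), with the binding protein gene Igfbp3 at 0.61 (SE 0.28). The median of insulin and IGF signalling was -0.04 without knockout replicate 1, 0.06 without wild-type replicate 1, 0.10 without knockout replicate 2 and 0.06 without knockout replicate 3, it was 0.19 on slide 1 and -0.05 on slide 2, and its call was lost without wild-type replicate 3 (0.13, adjusted p = 0.0772). The list of other imprinted genes had 11 of 15 members higher with a median of 0.07 (adjusted p = 0.0272, and adjusted p = 0.527 with an estimated correlation). Of these Dlk1, a Notch ligand of the fetal imprinted network, rose when adjusted over the list alone (1.97, SE 0.35, adjusted p = 0.013), and 0 did over all genes; it was well above background on 1 wild-type array and on 3 knockout arrays. The imprinted list had medians of -0.21 on slide 1 and -0.04 on slide 2, was -0.02 without knockout replicate 1 and 0.03 without wild-type replicate 2, and lost its call without knockout replicate 2 (0.08, adjusted p = 0.0747), wild-type replicate 3 (0.06, adjusted p = 0.229) or knockout replicate 3 (0.03, adjusted p = 0.0518). Genes that flank H19 were not shifted (median 0.02, adjusted p = 0.279), nor were let-7 targets (-0.04, adjusted p = 0.593), which H19 is known to affect by binding let-7, nor the polycomb repressive complex 2 (-0.02, adjusted p = 0.667), whose catalytic gene Ezh2 differed by 0.10 (SE 0.19).

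The genes of the circadian clock had a median of 0.25 with 9 of 14 higher (adjusted p = 0.00746, and adjusted p = 0.627 with an estimated correlation), with Nr1d1 at 0.68 (SE 0.19) and Bhlhe40 at 0.60 (SE 0.19). Without wild-type replicate 3 the median was -0.09 (adjusted p = 0.144), without wild-type replicate 2 it was 0.44 and without wild-type replicate 1 it was 0.06. On slide 1 it was 0.49 and on slide 2 -0.0046. Relative to each gene's mean over the 6 arrays, the list averaged -0.34, 0.48 and -0.56 in wild-type replicates 1, 2 and 3, so wild type held both extremes, and 0.23, 0.08 and 0.11 in knockout. Arntl read -0.82 in wild-type replicate 2 and 2.11 to 2.85 elsewhere, and Dbp 6.84 against 3.37 to 5.40. The sources used here do not say whether the hearts were collected at the same time of day. The cytosolic ribosomal proteins were higher in 35 of 52 cases with a median of 0.03, a mean of -0.01 and an upward test (adjusted p = 0.0256, and adjusted p = 0.888 with an estimated correlation). The ribosomal call was lost without wild-type replicate 1 (-0.01, adjusted p = 0.446), knockout replicate 1 (-0.05, adjusted p = 0.603) or wild-type replicate 2 (0.000343, adjusted p = 0.0647), and the median was 0.10 without knockout replicate 2 and 0.09 without wild-type replicate 3. On slide 1 it was 0.27 and on slide 2 -0.09.

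Genes of energy metabolism and contraction were not shifted. The medians were -0.02 for the sarcomere (adjusted p = 0.732), -0.12 for skeletal and embryonic muscle isoforms (adjusted p = 0.704), -0.07 for ion channels and gap junctions (adjusted p = 0.956), -0.10 for fatty acid oxidation (adjusted p = 0.666), 0.02 for glycolysis (adjusted p = 0.383), -0.05 for oxidative phosphorylation (adjusted p = 0.704), 0.01 for the tricarboxylic acid cycle (adjusted p = 0.454) and 0.03 for mitochondrial biogenesis and dynamics (adjusted p = 0.26). Antioxidant genes were not shifted as a list (median -0.09, adjusted p = 0.45), yet the metallothionein gene Mt2 (-0.74, SE 0.17) and Gclm, of glutathione synthesis (-0.71, SE 0.18), fell when adjusted over the list alone, against 0 over all genes. The glucocorticoid list (median 0.11, mean -0.04, adjusted p = 0.666) held 2 genes that fell when adjusted over the list alone, Pdk4, an inhibitor of pyruvate oxidation (-0.95, SE 0.21), and Mt2, and 0 over all genes. Adjusted over the fatty acid oxidation list, to which it also belongs, Pdk4 did not pass (adjusted p = 0.0826). The autophagy and lysosome list had a median of 0.04 (adjusted p = 0.106), ubiquitin and proteasome 0.02 (adjusted p = 0.14), inflammation and NF-kB 0.06 (adjusted p = 0.103) and the cell cycle -0.09 (adjusted p = 0.786). Of the remaining cell types, endothelial markers had a median of 0.03 (adjusted p = 0.135), smooth muscle and pericyte markers 0.12 (adjusted p = 0.136), Schwann cell markers 0.00275 (adjusted p = 0.667), neutrophil markers -0.98 (adjusted p = 0.165), erythroid and platelet markers 0.16 (adjusted p = 0.904) and adipocyte markers 0.44 (adjusted p = 0.168). The list of Y-linked genes and Xist had a median of 0.01 (adjusted p = 0.59). Its 3 measured members were the Y-linked Uty, Ddx3y and Eif2s3y, so Xist was not tested.

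In all, 18 of 43 lists were shifted at the preset correlation of 0.01, 15 upward and 3 downward. All 18 were shifted with slide as a block, at the same preset correlation. The estimated correlation was 0.91 for fibroblast markers, 0.29 for immediate early and heat shock genes and -0.05 for the p53 list. Upward and downward are relative to the other genes, and the median of all genes was -0.05. Of the 18, 0 passed with an estimated correlation, 0 with the rotation test fry and 7 with preranked GSEA, and 7 had medians on both slides with the sign of the median over all arrays. Without wild-type replicate 3, 10 lists were shifted, 8 of them among the 18.

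Of the 8 genes past the threshold, 4 lay on chromosome 9. Genes with an unadjusted p under 0.005 made up 19 of 1130 on that chromosome (1.68%), against 0.235% to 1.12% on the others. Chromosome Y was left out of the low end of that range. Within it, 6 of 41 genes from 85 to 90 Mb had such a p (mm9), and from 75 to 110 Mb it was 14 of 316, of which 8 were higher and 6 lower in knockout, among them Klhl31 and Snap91 (lower) and Pxylp1 and Abhd14b (higher). This stretch was singled out after its values were seen.

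**Figure D3:**
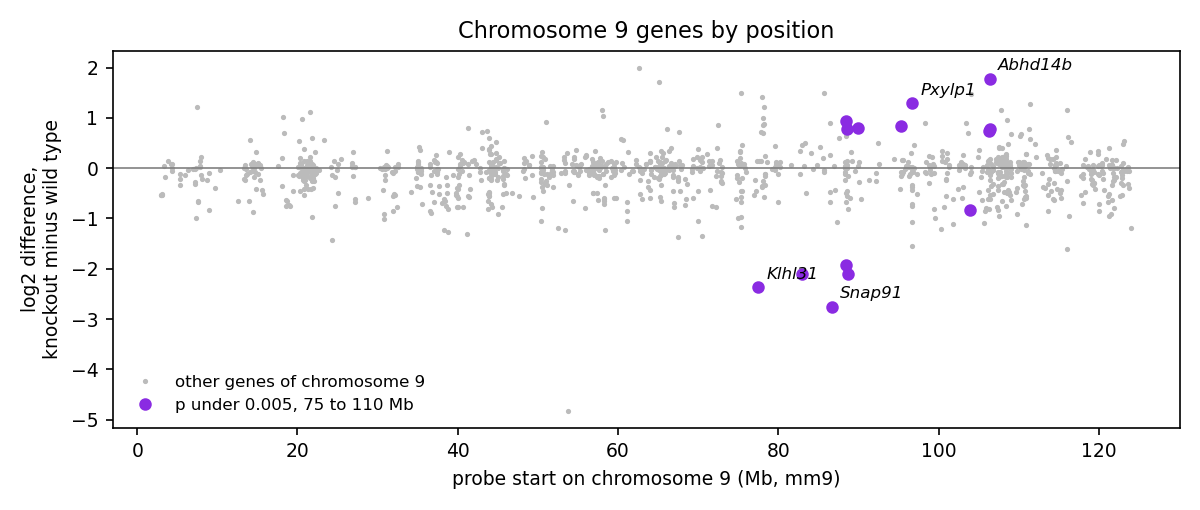
The horizontal axis is the probe start on chromosome 9 in Mb (mm9) and the vertical axis the log2 difference of each gene, knockout minus wild type; purple points are the 14 genes with p under 0.005 from 75 to 110 Mb. Of these 8 were higher and 6 lower, with Snap91 at -2.75 and Abhd14b at 1.78.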

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

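Leaving out genes of chromosome 9 was chosen only after the results were seen; the other alternatives were not. H19 kept its direction and its adjusted p under 0.05 in every alternative that gave it a value, with log2 differences from -7.28 to -4.19; the filter asking for all 6 arrays gave it none, since it was dim in knockout. The 8 changed genes became 3 with quantile normalization and 3 with the deposited values (2 of the 8 among them in each), 119 with scaling to the median of all probes, 1 without a filter on dim probes, 1 with slide as a block, 5725 with array weights and 1424 at an unadjusted p under 0.05 and 1.5-fold (180 up, 1244 down). The array weights rest on wild-type replicate 2 and knockout replicate 3, with weights of 5.65 and 6.91, from an estimate that did not converge. Without genes of chromosome 9, 1 gene passed, H19. Angptl4 (-1.99, SE 0.18), Manba (2.10, SE 0.18) and Tmem100 (2.36, SE 0.22) kept their differences and SE, at adjusted p from 0.0746 to 0.0809: the adjustment divides by the rank of p, and 4 of the 8 passing genes had been left out. Instead of 18 shifted lists there were 11 with quantile normalization and 11 with the deposited values (10 of the 18 among them in each). Probes well above background on all 6 arrays gave 9 (all among the 18), array weights 10 (7 among them) and no filter on dim probes 23 (16 among them). There were 0 with an estimated correlation, 0 with fry and 7 with preranked GSEA (all among the 18). Leaving out 1 array gave 1 to 4 genes and 10 to 20 lists. Unless the construction shows it, the cause was not tested. The higher share of genes at an unadjusted p under 0.05 was 13.4% here, 38.4% with quantile normalization, 37.9% with the deposited values and 86.6% with scaling to the median of all probes, which moved the median of all genes from -0.05 to 0.37.

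The replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.217, -0.051 and 0.037, and not every array correlated best with its own number. A fit with the replicate block left 1 gene, H19, and 18 lists.

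Values of single genes and list medians changed sign as follows, and the cause was not tested. With scaling to the median of all probes, to be read against the shift of all genes, Ifi44 was 0.0255, Tesc 0.411, Myh6 0.206, Ankrd1 0.365, Atp2a2 0.381 and Ryr2 0.395, and list medians were 0.397 for the sarcomere, 0.302 for skeletal and embryonic muscle isoforms, 0.356 for ion channels and gap junctions, 0.321 for fatty acid oxidation, 0.372 for oxidative phosphorylation, 0.321 for atrial markers, 0.326 for antioxidant genes, 0.333 for the cell cycle, 0.129 for interferon response, 0.385 for let-7 targets and 0.404 for polycomb repressive complex 2. With quantile normalization the sarcomere (cardiomyocyte markers) was 0.0171, the tricarboxylic acid cycle -0.00199, polycomb repressive complex 2 0.00907, ubiquitin and proteasome -0.00405 and Y-linked genes and Xist -0.0128. With the deposited values the sarcomere was 0.0146, the tricarboxylic acid cycle -0.00045, mitochondrial biogenesis and dynamics -0.00386, polycomb repressive complex 2 0.012 and Y-linked genes and Xist -0.0162. Normexp gave Tesc 0.0234 and the sarcomere 0.00769. The filter on all 6 arrays gave inflammation and NF-kB -0.129 and polycomb repressive complex 2 0.00339. The mean of a gene's probes gave Cdkn1a -0.139, Atp2a2 0.00361, mitochondrial biogenesis and dynamics -0.0132 and genes flanking H19 -0.0144. Array weights gave Nppa -0.0532, Myh7 -0.225, Acta1 -0.302, Atp2a2 0.00454, Ryr2 0.148, Postn -0.407, hypertrophy and fetal program -0.0742, calcineurin and NFAT -0.0521, TGF-beta signalling and targets -0.0227, smooth muscle and pericyte markers -0.0661, Schwann cell markers -0.264, the cell cycle 0.205, genes flanking H19 -0.0015, circadian clock -0.465 and glucocorticoid response -0.0983. Without genes of chromosome 9, endothelial markers were -0.0113.

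Leaving out each array in turn gave ranges of -0.158 to 0.0938 for Tesc, -0.0264 to 0.104 for Nppa, -0.299 to 0.502 for Myh7, -0.248 to 0.212 for Acta1, -0.122 to 0.0868 for Atp2a2, -0.0144 to 0.207 for Pln, -0.149 to 0.12 for Ryr2, -0.0329 to 0.85 for Col3a1, -0.416 to 0.692 for Postn and -0.00323 to 0.262 for Ezh2. For list medians they were -0.067 to 0.226 for hypertrophy and fetal program, -0.103 to 0.0621 for the sarcomere (cardiomyocyte markers), -0.0145 to 0.149 for calcium handling, -0.0383 to 0.0878 for calcineurin and NFAT, -0.223 to 0.056 for ion channels and gap junctions, -0.179 to 0.0298 for fatty acid oxidation, -0.0713 to 0.0692 for glycolysis, -0.134 to 0.0553 for oxidative phosphorylation, -0.103 to 0.108 for the tricarboxylic acid cycle and -0.13 to 0.157 for mitochondrial biogenesis and dynamics. They were -0.164 to 0.271 for endothelial markers, -0.0869 to 0.16 for smooth muscle and pericyte markers, -0.00589 to 1.01 for lymphocyte markers, -1.25 to 1.37 for erythroid and platelet markers, -0.249 to 0.386 for Schwann cell markers and -0.0706 to 0.98 for adipocyte markers. For the cell cycle the range was -0.276 to 0.087, for inflammation and NF-kB -0.108 to 0.133, for other imprinted genes -0.0221 to 0.0763, for genes flanking H19 -0.0246 to 0.0483, for let-7 targets -0.087 to 0.0179 and for polycomb repressive complex 2 -0.101 to 0.0304. For interferon response it was -0.464 to -0.145, so the median kept its sign. A list also counted as changed where the direction of its test turned and it was called in either setting. For insulin and IGF signalling it was -0.0388 to 0.143, for autophagy and lysosome -0.0855 to 0.101, for ubiquitin and proteasome -0.095 to 0.0955, for cytosolic ribosomal proteins -0.0455 to 0.1001, for the circadian clock -0.0946 to 0.438, for glucocorticoid response -0.0863 to 0.205 and for Y-linked genes and Xist -0.0784 to 0.133. Apart from these changes of sign or test direction, 1148 values of single genes or lists kept their direction and side of the threshold, 118 lost a call and 74 gained one under alternatives that keep all arrays, and 486, 57 and 20 did so when 1 array was left out.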

Other observations

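The tests of chance placement, dim probes, cell composition and other splits of the arrays were chosen only after the results were seen; the tests of a chromosome 9 segment, of a second atrial list and of PPAR targets were written before their results. Erythroid and platelet markers stood high in wild-type replicate 1 and knockout replicate 2, averaging 1.86 and 2.21 (log2, relative to each gene's mean over the 6 arrays), against -1.86 in knockout replicate 1. In wild-type replicate 2 the clock genes stood apart: Arntl read -0.82 there and 2.11 to 2.85 on the other arrays, Dbp 6.84 against 3.37 to 5.40, and Per2 1.62 against -2.90 to -0.05. Ndufa6 and Rps9, each read by 1 probe, were low on the array of knockout replicate 3 alone, at -1.99 against 5.67 to 6.27 and 1.22 against 7.35 to 7.81.

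On chromosome 9, 14 genes from 75 to 110 Mb had p under 0.005, among them Klhl31, Snap91, Hmgn3 (-2.11) and Ctsh (0.80), named after their values were seen. Only the highest 5-Mb bin, 85 to 90 Mb with 6 of 41 such genes, was tested against shuffled gene positions (share as high 2e-04 of 10000 shuffles), and the wider stretch was not. Shuffling ignores that neighbours can vary together: the other split of wild-type replicate 1 with knockout replicates 1 and 3 gave 14 of 134 genes at chromosome 17, 35 to 40 Mb, which holds 17 H2 genes. The binomial score of that bin was 11.9, against 6.32 for the chromosome 9 bin in the real split. How many of the 14 genes in the chromosome 17 bin are H2 genes was not examined. The highest bins of the remaining splits scored from 1.92 to 3.27. A stronger cluster thus arose in 1 split that mixes the genotypes, and the share of shuffles does not tie the chromosome 9 cluster to genotype. A scaling difference of dim probes is argued against only weakly by the directions, 8 higher and 6 lower in the region and 33 and 108 elsewhere (Fisher's exact p = 0.0109). That test treats neighbouring genes as independent, the brightness of the probes was not examined, and the 4 genes of the region past the threshold were all lower. A candidate explanation is a segment of another strain or donor carried by one genotype: genes of the region with p from 0.005 to 0.05 were also more frequent than elsewhere, 13.2% against 7.12% (odds ratio 1.99, 95% interval 1.38 to 2.80, Fisher's exact p = 0.000183). Sequence differences under the probes or true expression differences of such a segment would both give this, and the strain of the mice is not given in the sources used here. The region was drawn around genes of smaller p in these same data. Fisher's test also treats neighbouring genes as independent, so its p does not decide for a segment. An effect of H19 on this region stays open and was not tested.

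For the atrial genes Myl7, Sln and Myl4, fewer atrial cells in the knockout preparations may be involved, but a second list of atrial markers did not decide it: its median was -0.31 with 6 of 8 lower (adjusted p = 0.340 by camera, over this list and the PPAR list). This list was less shifted than those 3 genes, and its members are also expressed in ventricle to a degree not measured here. An effect of genotype on atrial genes of the ventricle stays open and was not tested.

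For the fibroblast and matrix lists, more non-cardiomyocyte cells in knockout replicate 2, despite the isolation by perfusion, may account for most of the shift: the fibroblast median was 0.17 without it and 0.60 with it, and 8 of 9 other non-cardiomyocyte lists were higher there than the median of the other arrays. A lower cardiomyocyte share in all knockout preparations would raise fibroblast and macrophage markers alike. The difference between these lists was 1.14 between genotypes (95% interval -0.43 to 2.71, exact permutation p = 0.1, the smallest 3 against 3 can give), a test that cannot decide it. Macrophage markers averaged -0.65, 0.44 and -0.53 in knockout replicates 1, 2 and 3, against -0.05, 0.09 and 0.70 in wild type. In knockout replicate 1 fibroblast markers (-0.32) lay within the wild-type range, and the sarcomere mean (0.13) was the highest of all arrays. It was -0.20 and 0.02 in knockout replicates 2 and 3. These values argue against a lower share in knockout replicate 1, and so in all knockout preparations. A genotype effect on these cells stays open and was not tested.

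As a hypothesis, the lower Angptl4 and Pdk4 (the latter past the threshold over 1 of its 2 lists and not over all genes), which are both targets of PPAR transcription factors, might belong to a lower activity of that pathway. Of a separate list of PPAR targets 9 of 9 were lower, with a median of -0.21 (adjusted p = 0.104 by camera, and adjusted p = 0.532 with an estimated correlation), which does not decide it. Of its members, Acot1 differed by -0.72 (SE 0.30), which did not pass over all genes.

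The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 8 genes, as many as 1 split did (itself), and the highest of the others 0; it gave 18 lists, which 4 splits reached, and the highest of the others gave 23.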
